A study of Homo sapiens with 18 samples.

How the data were processed

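RNA sequencing of RPE-1 cells, an hTERT-immortalized human retinal pigment epithelial line, was re-analysed from the gene tables that the authors deposited. The 18 libraries form 6 groups of 3: a control siRNA (siControl), an siRNA against MLX (siMlx) and an siRNA against MLXIP, the gene of MondoA (siMondoA), each in untreated cells and in cells given doxorubicin (DXR). Per the labels' protocols, cells were transfected with Lipofectamine RNAiMax for 2 days and DXR was then given at 150 ng/ml for 3 days. RNA was purified with RNeasy Plus and libraries were made with the TruSeq Stranded mRNA kit. Groups were taken from the labels. The library names also carry the tags D0 for untreated and D5 for DXR libraries. The labels do not say what these tags mean, so a difference in harvest day between untreated and DXR cells is open. The labels do not say either that the replicates of a group are separate cultures, and p-values measure only the spread between these libraries.

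Per the submitters' processing notes, reads were written with bcl2fastq, aligned to GRCh38 with TopHat2 2.1.1 and summarised per gene. The program that counted reads, the gene annotation and the strand setting are not given in the sources used here. Genes that overlap or lie antisense to another gene are therefore uncertain. The authors deposited a table of read counts per gene and a table of RPKM (reads scaled by gene length and mapped reads) for the same libraries. The count table was checked to hold whole numbers, and each deposited RPKM value was checked against its count, with the implied gene length whole within 0.01 bases for all 24846 genes with a count. The tables list 33121 genes, of which 8275 have no count in any library and none is a mitochondrially encoded gene. Of the listed names, 23574 are current symbols in GENCODE release 29, 1603 are older symbols and 7944 match no symbol there. The unmatched names hold 0.404% of counts. Older names were read under their current symbols (RUBCN is listed as KIAA0226). GENCODE coordinates on GRCh38 were used for the positions printed here.

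Total counts per library ran from 15503423 to 29219280, and between 16768 and 18492 genes had a count in a library. Over the 18 pairs of replicates, the chi-square per degree of freedom, in which abundant genes weigh most, was 3.9 to 17.55, where counting error alone gives about 1. Intervals and floors printed here cover counting error only. A group's floor was 3 counts over its 3 libraries.

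Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 13676 of the listed genes. Libraries were scaled with TMM, and all libraries were fitted with 1 mean per group and quasi-likelihood dispersions, giving 12 residual degrees of freedom and a biological coefficient of variation of 7.4%. Contrasts were tested with edgeR's two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The 5 main contrasts were each siRNA against siControl, in untreated and in DXR-treated cells, and DXR against untreated with siControl. The other contrasts were DXR against untreated with each siRNA, siMondoA against siMlx in each condition, and the interaction of each siRNA with DXR. Levels are in CPM (counts scaled to library size) after TMM, as mean and SD of 3 libraries, and SE is the standard error of the fitted log2 fold change.

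Groups, comparisons, tests, alternatives, the rule for naming genes and 28 gene lists were fixed before the data were examined. The rule named 14 genes in every comparison, among them MLXIP, MLX, TXNIP, PRDX3 and RUBCN. For each main comparison it added the 10 genes with the largest fold change in each direction (5 in the other comparisons) among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. Chance alone gives no overlap for 10% of unchanged genes with 3 libraries against 3. It also named up to 4 members with the smallest p of each list described. Lists with at least 5 tested genes, 26 of the 28, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance in one direction, were run as alternatives. For each list, members past the test were also counted with p adjusted over the list alone.

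The similarity of effects was measured across genes as the correlation and covariance of log2 fold changes. Comparisons that share siControl libraries were set beside 100 simulated draws of unchanged groups with shared controls, and beside comparisons that share no library. The model, the list tests and the similarity measure were also tested on simulated data with known changes.

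The alternatives were upper-quartile and RLE scaling, DESeq2 1.42.0, no low-count filter, a filter of 1 CPM in 3 libraries, a fit of the compared groups alone, replicate number as a block, limma on the log2 of the deposited RPKM with a pseudocount of 1 or 0.1 and with a filter of 1 RPKM, and leaving out each library in turn. List tests without MLX and MLXIP were chosen after seeing the data. Replicate numbers were checked as possible pairs, since the labels do not say what they mark. Each contrast was also recomputed under other splits of the same libraries. For 12174 tested genes with an annotated 3′ UTR of at least 50 bases, each 7-base word held by at least 100 genes was tested for lower fold changes in the genes holding it, after UTR length and AU content, and compared with 200 shuffles of the fold changes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for this and for the figures. A list of mitochondrially encoded genes and one of photoreceptor genes were fixed too. The tables list none of the first and 3 tested genes of the second, so neither was tested.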

Results

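Poly(A)-selected, stranded RNA libraries were sequenced from RPE-1 cells. Cells received a control siRNA (siControl), an siRNA against MLX (siMlx) or an siRNA against MLXIP (siMondoA), and were then left untreated or given doxorubicin (DXR), a DNA-damaging drug, at 150 ng/ml for 3 days. MLXIP encodes MondoA, a glucose-responsive transcription factor, and MLX encodes its DNA-binding partner. Each of the 6 groups had 3 libraries. Total counts per library were 19305200 to 29219280 with siControl, 17061466 to 19097476 with siMlx and 15503423 to 22854434 with siMondoA in untreated cells. In DXR-treated cells they were 18342883 to 21858817. The first principal component of the log2 CPM of all tested genes held 50.7% of their variance and parted all DXR libraries, at 33.2 or above, from all untreated libraries, at -18.2 or below. The second, with 17.8%, placed the siMlx libraries at 29.8 or above and every other library at 6 or below. The lowest correlation between replicates was 0.994.

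MLXIP (chromosome 12, 122078722 to 122147347, GRCh38) was measured at 68.7 ± 4.6 CPM (mean ± SD, n = 3 libraries here and below) in untreated siControl cells, at 77.1 ± 7.5 with siMlx and at 3.85 ± 0.65 with siMondoA. In DXR-treated cells it was at 64.6 ± 1.7, 69.7 ± 2.6 and 2.36 ± 0.65 in the same order. Its 3 untreated siMondoA libraries stood at 3.34, 4.57 and 3.63 CPM and its 3 DXR-treated siMondoA libraries at 1.63, 2.58 and 2.86. With siMondoA, MLXIP was lower by log2 -4.13 (SE 0.12, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.16e-15) in untreated cells, which left 5.71% of the control level, and by -4.77 (SE 0.13, adjusted p = 3.15e-15) in DXR-treated cells. MLX (chromosome 17, 42567068 to 42573239) was at 26.3 ± 0.95 CPM with siControl and 7.0 ± 0.18 with siMlx in untreated cells, and at 26.5 ± 0.21 and 5.52 ± 0.53 in DXR-treated cells. With siMlx it was lower by log2 -1.91 (SE 0.07, adjusted p = 6.94e-14) and -2.27 (SE 0.08, adjusted p = 5.78e-14) in the 2 conditions. With siMondoA, MLX was higher, at 49.2 ± 2.6 CPM in untreated cells (log2 0.91, SE 0.06, adjusted p = 5.26e-10) and 43.8 ± 1.4 in DXR-treated cells (log2 0.72, SE 0.06, adjusted p = 5.72e-08). MLXIP did not pass the test with siMlx (log2 0.17, adjusted p = 0.119, untreated, where it passed without untreated siMlx replicate 3, at 0.0424; log2 0.11, adjusted p = 0.372, DXR). DXR left MLXIP at log2 -0.09 against untreated siControl cells (adjusted p = 0.406). The paralogue MLXIPL had 0 to 2 counts per library and was not tested.

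**Figure D1:**
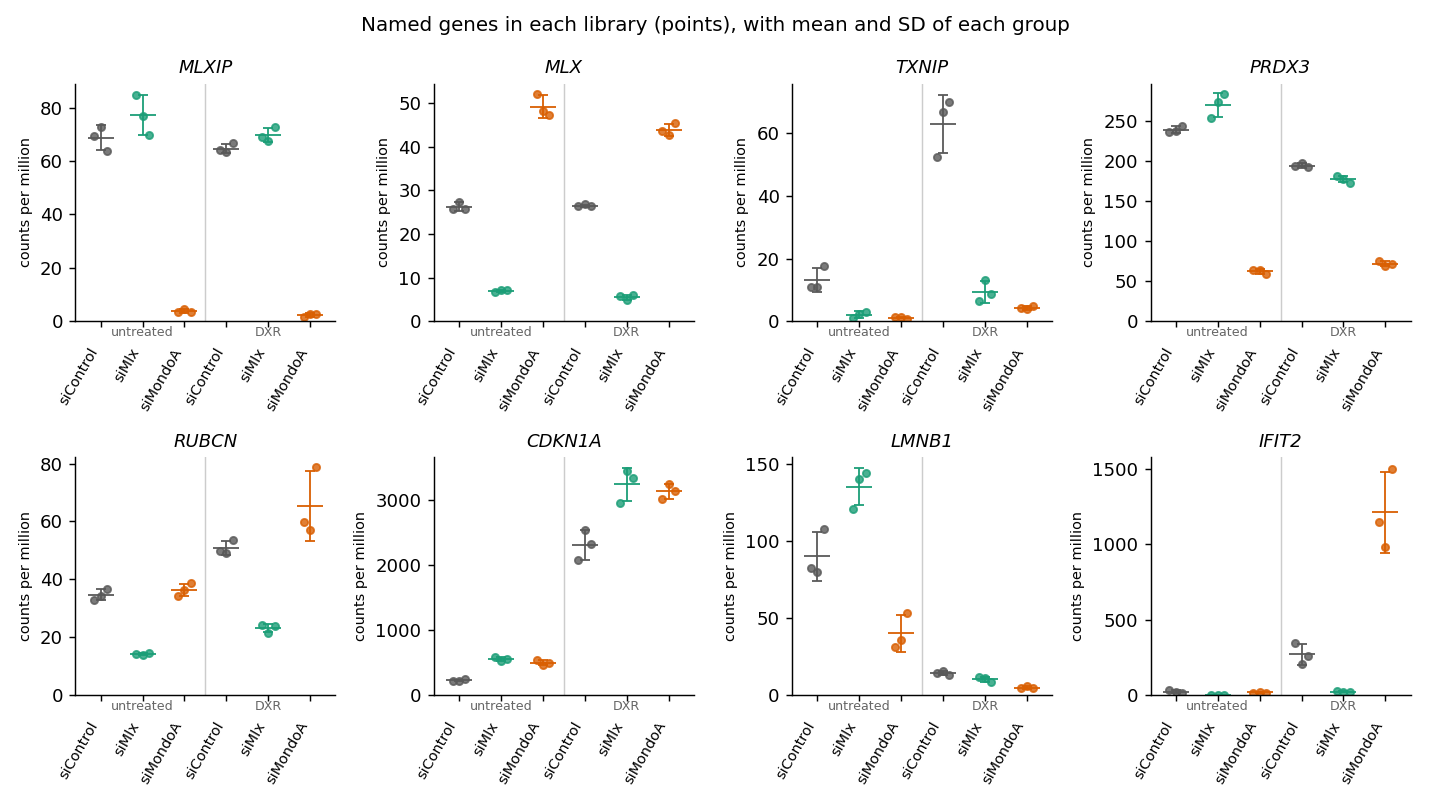
Level of 8 named genes in each of the 18 libraries, in CPM on a linear axis from 0, with untreated groups on the left and DXR groups on the right of each panel. Points are libraries, and horizontal marks with bars are group means with SD (n = 3). MLXIP stays below 5 CPM in all 6 siMondoA libraries, MLX is lowest in the 6 siMlx libraries, and PRDX3 is lowest in the 6 siMondoA libraries.

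The first comparison asked which transcripts depend on MondoA in untreated cells. TXNIP, which encodes the thioredoxin-interacting protein and is a known MondoA target, fell from 13.2 ± 3.9 to 1.19 ± 0.25 CPM with siMondoA (log2 -3.46, SE 0.32, edgeR adjusted p = 3.56e-08). PRDX3 (chromosome 10, 119167703 to 119178833), the mitochondrial peroxiredoxin, fell from 239 ± 4.4 to 62.4 ± 3.2 CPM (log2 -1.94, SE 0.05, adjusted p = 9.71e-16). The listed genes of DNA replication and of mitosis fell (adjusted p = 0.555 and 0.876 for the lists with an estimated correlation), and CDKN1A, which encodes the cell-cycle inhibitor p21, rose by log2 1.13 (SE 0.08, adjusted p = 4.68e-10). LMNB1, which encodes lamin B1, fell by log2 1.18 (SE 0.15, adjusted p = 3.25e-06). RUBCN, which encodes the autophagy inhibitor Rubicon, was not changed past the test (log2 0.07, adjusted p = 0.601), and neither was TFEB, a regulator of lysosomal genes (-0.18, adjusted p = 0.213). ARRDC4, another MondoA target, had 1 count in the siMondoA and 3 in the siControl libraries, too few for a fold change.

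Besides MLXIP and TXNIP, the genes with the largest falls were BTBD10, from 42.4 to 3.85 CPM (log2 -3.47, SE 0.08, adjusted p = 2.19e-16), and PABIR2 (listed as FAM122B, -3.40, SE 0.15). The mitotic kinase gene MELK fell from 68.5 to 8.5 CPM (-3.03, SE 0.16, adjusted p = 1.35e-11). ARHGAP19 (-2.99), DMAC2 (listed as ATP5SL, -2.88), the cyclin gene CCNE2 (-2.85), PLSCR4 (-2.77) and FAM111B (-2.76) followed, with adjusted p of 1e-07 or below. FAM111B stood at -3.38 without untreated siMondoA replicate 3. The largest rises were in SPEF1 (2.76), TTC29 (2.69), RBM47 (2.69) and FANK1 (2.63), all from about 1 CPM to between 5.08 and 8.01. IL6R, the interleukin-6 receptor gene, rose from 15.3 to 75.2 CPM (2.29, SE 0.17, adjusted p = 1.99e-09), TNFRSF11B, which encodes osteoprotegerin, from 8.97 to 39.4 CPM (2.15, SE 0.20) and SEMA3D from 17.2 to 69.0 CPM (2.0, SE 0.14). PIERCE1 (2.15), C17orf97 (2.13) and NR4A3 (2.03) completed the 10. CDKN2A was higher (0.38, SE 0.11, adjusted p = 0.0093). MKI67, a proliferation marker, was lower (-1.37, SE 0.32, adjusted p = 0.00138) and stood at -1.96 without untreated siMondoA replicate 3. IL6 was higher by 0.50 (adjusted p = 0.0478), a call that ended with the 2 groups fitted alone (0.121), with DESeq2 (0.0552) and without untreated siControl replicate 1 (0.167) or 3 (0.22) or siMondoA replicate 2 (0.334).

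Of the fixed lists, 2 passed camera with siMondoA in untreated cells, both lower. All 49 tested genes of DNA replication and E2F control fell (49 also when adjusted over the list alone), with a median of log2 -1.53 (camera adjusted p = 2.04e-33, and adjusted p = 0.555 with an estimated correlation). UHRF1 stood at -1.70, CDC6 at -2.29, CDT1, a replication licensing factor, at -2.32, and E2F1 at -2.42. All 43 G2/M and mitosis genes fell (43 over the list alone), with a median of -1.38 (camera adjusted p = 1.45e-16, and adjusted p = 0.876 with an estimated correlation), among them CCNA2 (-2.04), NCAPH (-1.97), ANLN (-1.68) and CDC20 (-1.51). Relative to the mean of untreated siControl libraries, the G2/M list stood at -1.72, -1.54 and -0.87 in the 3 siMondoA libraries, against -0.11, -0.15 and 0.26 in the siControl libraries.

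Lists on the series title's themes did not pass camera. Of 43 autophagy genes, 24 rose and 6 fell (25 and 7 over the list alone), with a median of 0.19 (camera adjusted p = 0.0989). WIPI2 rose by 0.35, while STX17 (-0.75), ATG12 (-0.59) and ATG7 (-0.54) fell. Of 47 lysosomal genes, 13 rose and 6 fell (median 0.06, adjusted p = 0.597). Of 77 nuclear-encoded subunits of oxidative phosphorylation, 15 rose and 5 fell (12 and 4 over the list alone; median 0.05, adjusted p = 0.492). Among 31 genes of mitochondrial dynamics, biogenesis and mitophagy, 9 rose and 10 fell (median -0.05, adjusted p = 0.984). Of 32 antioxidant genes, 8 rose and 5 fell (median 0.07, adjusted p = 0.86), with PGD, of the pentose phosphate pathway, at 0.80 and its neighbour in that pathway TKT at 0.51. Among 13 glucose-responsive MondoA/ChREBP targets none rose and 4 fell (3 over the list alone), TXNIP and KLF11 (-1.15) among them, and the list did not pass (median -0.07, or -0.05 with ARRDC4 at its bound, adjusted p = 0.616). The MAX-MLX network had 4 genes higher and 4 lower of 10, with a median of 0.05, a mean of -0.48 and a test direction lower (adjusted p = 0.206). MAX (-0.59) and MYC (-0.57) were among the lower ones. Of 40 p53 targets, 19 rose and 4 fell (median 0.23, adjusted p = 0.0989, and 0.0486 without untreated siMondoA replicate 2). ZMAT3 (-1.39) and the caspase activator APAF1 (-1.11) were among those that fell.

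The other lists did not pass in this comparison either. Of 34 senescence-associated secretory genes, 11 rose and 6 fell, with a median of 0.01 and a mean of -0.06 (camera adjusted p = 0.984), TNFRSF11B being highest among the named ones and FGF2 lowest (-2.12). None of 42 interferon-stimulated genes rose and 5 fell, or none when adjusted over the list alone (median -0.38, or -0.39 with genes near the floor at their bound, adjusted p = 0.616). Of 23 NF-kB targets 2 rose and 9 fell (3 and 9 over the list alone; median -0.25, adjusted p = 0.686), of 24 glycolysis genes 3 rose and 7 fell (median -0.07, adjusted p = 0.616), and of 25 HIF targets 5 rose and 7 fell (median 0.00, mean -0.20, adjusted p = 0.757). Of 33 ATF4 targets 9 rose and 6 fell (median 0.07, adjusted p = 0.989), with the cystine transporter gene SLC7A11 at 1.53 and the mitochondrial folate enzyme gene MTHFD2 at -1.45. Medians were 0.75 for 13 histone genes (adjusted p = 0.148), 0.06 for 25 cholesterol genes (0.632), 0.00 for 25 endoplasmic reticulum stress genes (0.984), 0.06 for 36 extracellular matrix genes (0.989), 0.00 for 74 cytosolic ribosomal proteins (0.984), -0.07 for 35 ribosome biogenesis genes (0.616) and 0.02 for 67 mitochondrial ribosomal proteins (0.616). Markers of other cell types did not pass as lists: 12 fibroblast markers had a median of 0.15 (0.733), and 7 blood and endothelial markers a median of 0.41 with a test direction lower (0.989). Retinal pigment epithelium markers had a median of 0.04 and a mean of -0.07 (0.733).

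In all, 6375 of the 13676 tested genes passed the test with siMondoA in untreated cells, 3185 higher and 3190 lower (3813 and 2813 with upper-quartile scaling), of which 315 were higher and 693 lower by at least 2-fold. Lower genes more often held certain 3′ UTR words: of 3438 genes holding at least 1 of the 3 words most associated with lower siMondoA fold changes in these same genes (the first is TCCAGTA) 36.6% were called lower, against 20.5% of 8736 genes holding none. BTBD10 held 3 of these words, CCNA2, UHRF1, FGF2, STX17 and MTHFD2 held 2, ZMAT3 held 3, and MLXIP, PABIR2, ARHGAP19, DMAC2, CCNE2, NCAPH, CDC6, MKI67, ATG12 and ATG7 held 1. PRDX3, TXNIP, LMNB1, MELK, PLSCR4, FAM111B, CDT1, E2F1, ANLN, CDC20, APAF1, KLF11, MAX and MYC held 0. Noncoding RN7SL1 and RN7SL2 together were at 11.8 to 30.6 CPM in untreated siControl libraries and at 3.42 to 6.11 in untreated siMondoA libraries, RN7SK at 6.7 to 11.7 and 2.0 to 3.4, and RNA45S5 at 26.8 to 48.7 and 12.2 to 16.6. Their means were lower in every other group, so each comparison with untreated siControl cells carries this difference.

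**Figure D2:**
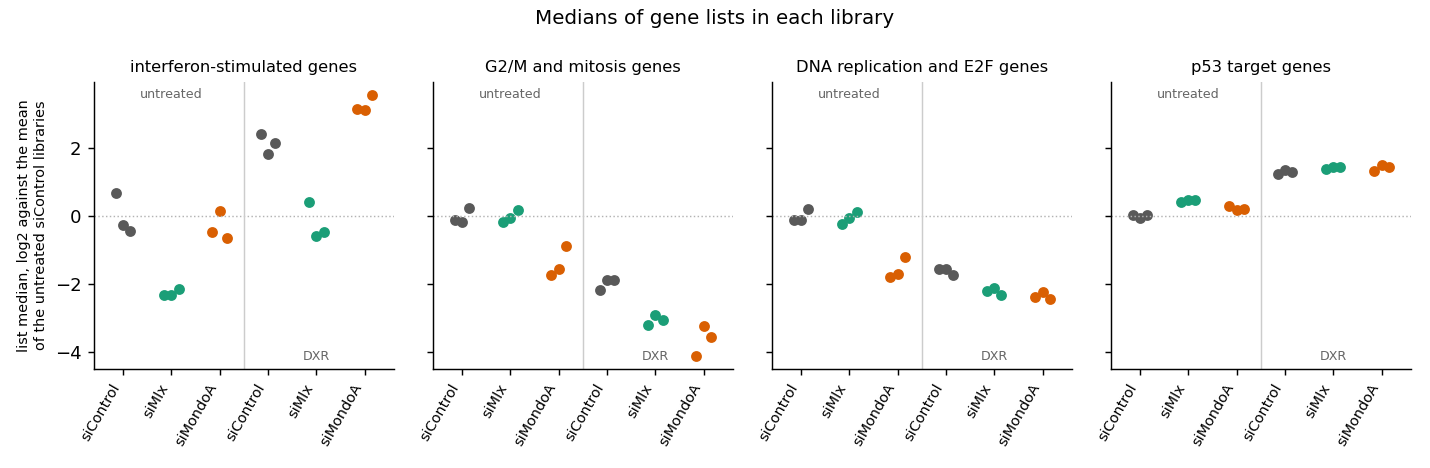
Median log2 level of 4 gene lists in each of the 18 libraries, relative to the mean of the untreated siControl libraries (dotted line at 0), with untreated groups on the left and DXR groups on the right. Each point is 1 library. The interferon-stimulated genes lie between -2.32 and -2.14 in untreated siMlx libraries and between 3.12 and 3.56 in DXR-treated siMondoA libraries.

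The second comparison asked which transcripts depend on MLX in untreated cells. Of 42 interferon-stimulated genes 39 fell with siMlx (adjusted p = 0.815 for the list with an estimated correlation). OAS1, a sensor of double-stranded RNA, went from 18.6 ± 14 to 0.225 ± 0.12 CPM (log2 -6.34, SE 0.97, edgeR adjusted p = 2.14e-05), and IFIT1 from 117 ± 86 to 2.35 ± 0.18 CPM (-5.65, SE 0.62, adjusted p = 3.32e-07). OAS2 had 3 counts with siMlx and 432 with siControl, a ratio of 106-fold lower (95% counting interval 36 to 515). TXNIP fell to 2.18 ± 0.98 CPM (-2.59, SE 0.29, adjusted p = 3.61e-07) and RUBCN (chromosome 3, 197671393 to 197749727) from 34.7 ± 1.9 to 14.2 ± 0.32 CPM (-1.29, SE 0.10, adjusted p = 3.38e-09). CDKN1A rose to 553 ± 26 from 228 ± 11 CPM (1.28, SE 0.08, adjusted p = 5.36e-11).

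The remaining large falls were in USP18 (-4.71), IFI44L (-3.97), IFITM1 (-3.85), IFI6 (-3.74) and IFIH1, the RNA sensor MDA5 (-3.41, SE 0.38, adjusted p = 3.47e-07), and, outside that group, in DCTD, a deoxycytidylate deaminase (116 to 12.3 CPM, -3.24, SE 0.06, adjusted p = 1.01e-17), and SPTLC3, a subunit of serine palmitoyltransferase (38.2 to 4.29 CPM, -3.15, SE 0.20). Untreated siControl replicate 1 had the highest interferon-stimulated levels of its group. Without it OAS1 stood at -5.46, OAS2 at -5.89, IFIT1 at -4.85, USP18 at -3.79, IFI44L at -3.25, IFITM1 at -2.98 and IFI6 at -2.99. Without untreated siMlx replicate 1, OAS2 stood at -7.44. The largest rises were in CDC42SE2, from 7.42 to 51.7 CPM (2.79, SE 0.09, adjusted p = 4.73e-15), the p53-induced apoptosis gene BBC3 (2.09 to 10.3 CPM, 2.28, SE 0.17), C4orf46 (2.12), NAT8L (5.07 to 22.0 CPM, 2.1, SE 0.12) and RPIA, a pentose phosphate pathway enzyme (4.56 to 19.1 CPM, 2.06, SE 0.12). ADAMTS5 (1.94), MEX3D (1.80), PALD1 (1.80), SOCS1, an inhibitor of cytokine signalling (1.78), and GPR157 (1.77) followed. LMNB1 was higher (0.58, SE 0.15, adjusted p = 0.0026). PRDX3 was higher by 0.18 (adjusted p = 0.0069; 0.0592 with no low-count filter). CDKN2A stood at 0.36 (adjusted p = 0.0127), a call that ended without untreated siControl replicate 1 (0.0567) or siMlx replicate 2 (0.098). TFEB stood at -0.29 (adjusted p = 0.0409). That call ended in 8 alternatives, with adjusted p up to 0.153, among them the fits without untreated siControl replicate 1 (0.125) or 2 (0.0755) and siMlx replicate 1 (0.141) or 2 (0.0928). IL6 (-0.14, adjusted p = 0.618) and MKI67 (0.20, adjusted p = 0.626) did not pass. ARRDC4, with 4 counts against 3, had a ratio of 1.81 (95% counting interval 0.307 to 12.4).

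With siMlx in untreated cells, 4 lists passed camera. None of 42 interferon-stimulated genes rose and 39 fell (39 over the list alone), with a median of -2.46, also with genes near the floor at their bound (camera adjusted p = 4.63e-12, and adjusted p = 0.815 with an estimated correlation). IRF9 (-2.36) and STAT2 (-1.83), subunits of the interferon-activated transcription factor ISGF3, and IFIT2 (-2.87) and IFIT3 (-2.82) were among them. Of 40 p53 targets 27 rose and 7 fell (27 and 8 over the list alone), with a median of 0.46 (adjusted p = 6.33e-05, and adjusted p = 0.491 with an estimated correlation), among them CDKN1A, BBC3, PHLDA3 (0.79) and BAX (0.59). Of 35 ribosome biogenesis genes 29 rose and 1 fell (30 and 1 over the list alone), with a median of 0.33 (adjusted p = 2.74e-05, and adjusted p = 0.491 with an estimated correlation), RRN3 (0.82) and DDX21 (0.52) among them. Of 33 ATF4 targets 20 rose and 4 fell, with a median of 0.37 (adjusted p = 0.013, and adjusted p = 0.843 with an estimated correlation), among them CHAC1 (1.73) and ATF4 itself (0.57). Autophagy genes did not pass as a list (12 of 43 higher and 14 lower, median 0.01, mean -0.10, adjusted p = 0.519), although STX17 (-1.36), ATG2B (-1.13) and CALCOCO2 (-1.08) fell. Of 47 lysosomal genes 4 rose and 21 fell (4 and 24 over the list alone; median -0.14, adjusted p = 0.201), with the lysosomal membrane gene LAMP2 at -1.11. The mitophagy receptor gene BNIP3L (-2.17, SE 0.07) and the mitophagy kinase gene PINK1 (-1.15, SE 0.08) fell, while the list of mitochondrial dynamics genes did not pass (median 0.05, adjusted p = 0.81). Glucose-responsive targets did not pass either (median 0.05, mean -0.24, adjusted p = 0.523), although ARRDC3 fell by 1.77.

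In all, 6553 genes passed with siMlx in untreated cells, 3410 higher and 3143 lower (3909 and 2833 with upper-quartile scaling), of which 288 were higher and 719 lower by at least 2-fold. Of 4210 genes holding at least 1 of the 3 words most associated with lower siMlx fold changes in these same genes (the first is CTGGTCA) 37.1% were called lower, against 17.9% of 7964 genes holding none. BNIP3L, ATG2B and LAMP2 held 3 of these words, MLX, OAS2, SPTLC3, IFIT2 and ARRDC3 held 2, TXNIP, RUBCN, IFI44L and CALCOCO2 held 1, and OAS1, IFIT1, USP18, IFITM1, IFI6, IFIH1, DCTD, IRF9, STAT2, IFIT3, PINK1, STX17 and TFEB held 0. RN7SL1 and RN7SL2 together were at 2.34 to 3.25 CPM in the untreated siMlx libraries, RN7SK at 2.23 to 2.9 and RNA45S5 at 17.4 to 41.9.

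The effects of both siRNAs were then set side by side, since MondoA binds DNA with MLX. Across the 13676 genes, which are not independent replicates, the 2 effects in untreated cells had a Pearson correlation of 0.149 (Spearman 0.13), and simulated unchanged groups with shared controls 0.46 (range 0.427 to 0.507). Those hold no effect, so 0.149 does not mean similarity below chance. The covariance was 0.055 against 0.019 in those simulations. Genes higher with both numbered 1091 (794 if the calls were independent), and genes lower with both numbered 972 (733 if independent). How much of that excess comes from the shared controls was not measured. In the simulations 0 genes passed the same way in both. The siMondoA effect in untreated cells and the siMlx effect in DXR-treated cells, which share no library, had a correlation of 0.223 (Spearman 0.214). The siMlx effect in untreated cells and the siMondoA effect in DXR-treated cells, also without a shared library, had one of -0.003 (Spearman 0.064, and -0.03 to 0.009 with 1 library left out).

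Tested directly in untreated cells, 8060 genes differed between siMondoA and siMlx, 3899 higher with siMondoA and 4161 lower. IL6R was higher with siMondoA (75.2 against 4.21 CPM, log2 4.16, SE 0.21, edgeR adjusted p = 1.66e-12), as were IFIT1 (4.87, SE 0.63, adjusted p = 1.5e-06), OAS1 (4.87, or 4.17 without untreated siMondoA replicate 2), SPEF1 (3.97) and IFITM1 (3.78, or 3.17 without that library). MLXIP (-4.30), BTBD10 (-3.41), B4GALT6 (-3.34, SE 0.10, adjusted p = 1.38e-15), DMAC2 (-3.25) and MELK (-3.03) were lower. So were PRDX3 (-2.11, SE 0.05, adjusted p = 2.02e-16) and LMNB1 (-1.76, SE 0.15, adjusted p = 7.94e-09), while RUBCN was higher with siMondoA (1.35, SE 0.10, adjusted p = 1.03e-09) and TXNIP did not pass (-0.87, adjusted p = 0.0915, and 0.000189 to 0.0478 in 5 alternatives). Among lists, 34 of 42 interferon-stimulated genes were higher (35 over the list alone; median 2.33, or 2.31 at the bound, camera adjusted p = 7.41e-07, and adjusted p = 0.817 with an estimated correlation). All 49 replication genes (median -1.40, adjusted p = 8.45e-19, and adjusted p = 0.453 with an estimated correlation) and 42 of 43 G2/M genes (median -1.36, adjusted p = 8.79e-10, and adjusted p = 0.763 with an estimated correlation) were lower with siMondoA. Autophagy genes were higher (22 of 43 higher and 6 lower, 22 and 7 over the list alone, median 0.13, adjusted p = 0.0352, and adjusted p = 0.453 with an estimated correlation), with ATG14 at 1.58 and ATG2B at 1.36. Both of these genes hold 3 of the words associated with lower siMlx fold changes, so an effect of those words is open. Histones were higher (9 of 13, median 1.15, adjusted p = 0.0209, and adjusted p = 0.453 with an estimated correlation) and ribosome biogenesis genes lower (29 of 35, median -0.38, adjusted p = 3.04e-05, and adjusted p = 0.453 with an estimated correlation). Lysosomal genes passed at an adjusted p of 0.0467 (22 of 47 higher and 1 lower, median 0.17, and adjusted p = 0.506 with an estimated correlation). Without untreated siMlx replicate 2 (0.0709) or 3 (0.0563) or untreated siMondoA replicate 1 (0.0688) or 2 (0.0516), and with the stricter filter (0.0614), they did not. ATF4 targets passed at 0.0467 (5 of 33 higher and 19 lower, median -0.40, and adjusted p = 0.817 with an estimated correlation), but not with the stricter filter (0.0638) or without untreated siMlx replicate 1 (0.0756) or 2 (0.0862) or untreated siMondoA replicate 3 (0.108).

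The response to DXR was measured in siControl cells. CDKN1A (chromosome 6, 36676460 to 36687339) rose from 228 ± 11 to 2310 ± 230 CPM (log2 3.34, SE 0.08, edgeR adjusted p = 6.33e-16), and the mitotic transcription factor gene FOXM1 went from 395 to 57.9 CPM (-2.77, SE 0.14, adjusted p = 1.08e-11). LMNB1, whose loss is a common mark of senescent cells, fell from 89.9 ± 16 to 14.4 ± 1.4 CPM (-2.64, SE 0.17, adjusted p = 2.27e-10), and CDKN2A rose by 0.43 (SE 0.11, adjusted p = 0.00333). TXNIP rose from 13.2 ± 3.9 to 63.0 ± 9.2 CPM (2.25, SE 0.21, adjusted p = 2.45e-08), and ARRDC4 had 73 counts against 3, a ratio of 31.3 (95% counting interval 10.3 to 155; fitted adjusted p = 3.29e-05). RUBCN (0.55, SE 0.09, adjusted p = 4.5e-05), TFEB (0.57, SE 0.11, adjusted p = 0.000138) and IL6 (0.95, SE 0.19, adjusted p = 0.00032) rose, PRDX3 (-0.30, SE 0.05, adjusted p = 4.78e-05) and MKI67 (-2.11, SE 0.33, adjusted p = 1.75e-05) fell, and GDF15 had 0 to 7 counts per library and was not tested.

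The antiviral gene RSAD2 had 483 counts against 3, a ratio of 207-fold higher (95% counting interval 70.5 to 1010). The fitted value without untreated siControl replicate 1 was 6.85, and 10.31 without replicate 3. The chloride channel regulator CLCA2, a p53 target, rose from 0.176 to 12.2 CPM (5.94, SE 0.34, adjusted p = 5.61e-11), IGFBP5, an insulin-like growth factor binding protein, from 2.69 to 61.5 (4.47, SE 0.50), COL4A4 from 4.91 to 84.0 (4.09, SE 0.25) and BTG2, an antiproliferative p53 target, from 1.89 to 31.2 (4.04, SE 0.13). LRATD1 (listed as FAM84A, 4.20), SPATA18 (4.15), OASL (3.98), LY6E (3.95) and COL4A3 (3.85) completed the 10. Without untreated siControl replicate 1, CLCA2 stood at 7.08, IGFBP5 at 5.55, LY6E at 4.60 and the fitted value of ARRDC4 at 7.59. The largest falls were in SOX11 (5.83 to 0.268 CPM, -4.42, SE 0.26, adjusted p = 8.65e-11), the primase gene PRIM1 (-2.93), E2F2 (-2.80), FOXM1, TRPV2 (-2.74), ADGRG1 (listed as GPR56, -2.71), SAPCD2 (-2.66), LMNB1 and the kinetochore gene NUF2 (-2.51). The antisense transcript TMPO-AS1 stood at -2.72, an uncertain value since the strand setting is not given.

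Of the lists, 12 passed camera with DXR in siControl cells. Of 40 p53 targets 37 rose and 1 fell, with a median of 1.29 (camera adjusted p = 9.13e-57, and adjusted p = 9.58e-05 with an estimated correlation), RRM2B (1.78) and the autophagy regulator gene DRAM1 (1.98) among them. Of 47 lysosomal genes 35 rose and 5 fell (36 and 5 over the list alone), with a median of 0.38 (adjusted p = 1.9e-07, and adjusted p = 0.0223 with an estimated correlation), GAA (1.74), SMPD1 (0.74) and LAMP1 (0.68) higher and GUSB (-1.12) lower. Of 13 histone genes 10 rose and 1 fell (median 1.54, adjusted p = 5.15e-08, and adjusted p = 0.0223 with an estimated correlation). These 3 lists kept their call with an estimated correlation, and the next 9 did not. Of 42 interferon-stimulated genes 41 rose (42 over the list alone; median 2.07, adjusted p = 4.8e-13, and adjusted p = 0.25 with an estimated correlation), IFIT2 (3.53) and the RNA sensor gene RIGI (2.36) among them. All 43 G2/M genes fell (median -1.99, adjusted p = 1.27e-30, and adjusted p = 0.14 with an estimated correlation), with KIF20A at -2.22 and CCNB2 at -2.34. Of 49 replication genes 47 fell (median -1.63, adjusted p = 1.2e-29, and adjusted p = 0.14 with an estimated correlation), with TK1 at -2.13 and MCM7 at -2.06.

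Of 34 senescence-associated secretory genes 21 rose and 6 fell with DXR (median 0.41, camera adjusted p = 1.69e-05, and adjusted p = 0.14 with an estimated correlation), IGFBP3 (1.62) and IGFBP7 (1.60) among them. Of 36 extracellular matrix genes 28 rose and 3 fell (28 and 4 over the list alone; median 0.78, adjusted p = 4.24e-08, and adjusted p = 0.226 with an estimated correlation), with POSTN, periostin, at 3.07 and COL12A1 at -0.94. Of 43 autophagy genes 23 rose and 8 fell (23 and 9 over the list alone; median 0.21, adjusted p = 0.0192, and adjusted p = 0.156 with an estimated correlation), GABARAPL1 (1.16), OPTN (0.94), WIPI1 (0.81) and MAP1LC3B (0.55) among those that rose. Of 23 NF-kB targets 11 rose and 4 fell (11 and 5 over the list alone; median 0.38, adjusted p = 0.0371, and adjusted p = 0.243 with an estimated correlation). That call ended without untreated siControl replicate 1 (0.0709) or DXR-treated siControl replicate 1 (0.0586). Of 35 ribosome biogenesis genes 24 fell and 2 rose (median -0.32, adjusted p = 4.15e-05, and adjusted p = 0.14 with an estimated correlation), FBL, fibrillarin, at -1.08. Of 67 mitochondrial ribosomal proteins 46 fell and 1 rose (48 and 1 over the list alone; median -0.28, adjusted p = 5.4e-06, and adjusted p = 0.242 with an estimated correlation). Subunits of oxidative phosphorylation did not pass (16 of 77 higher and 28 lower, median -0.08, adjusted p = 0.32), nor did antioxidant genes (median -0.13, adjusted p = 0.314), in which NQO1 (-1.14) and GSR (-0.80) fell. Markers of blood and endothelial cells (median 0.86, adjusted p = 0.454) and of fibroblasts (median -0.13, mean 0.28, adjusted p = 0.601) did not pass as lists. The fibroblast gene DCN rose by 2.5, and the macrophage gene LYZ had 25 counts against 3, a ratio of 10.7 (95% counting interval 3.27 to 55.5).

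In all, 7756 genes passed with DXR in siControl cells, 3841 higher and 3915 lower, of which 1070 were higher and 623 lower by at least 2-fold. RN7SL1 and RN7SL2 together were at 11.8 to 30.6 CPM in untreated and 2.63 to 3.55 CPM in DXR-treated siControl libraries, where RN7SK was at 2.93 to 3.95 and RNA45S5 at 10.7 to 14.1. Whether harvest day also differs (tags D0 and D5) is open.

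**Figure D3:**
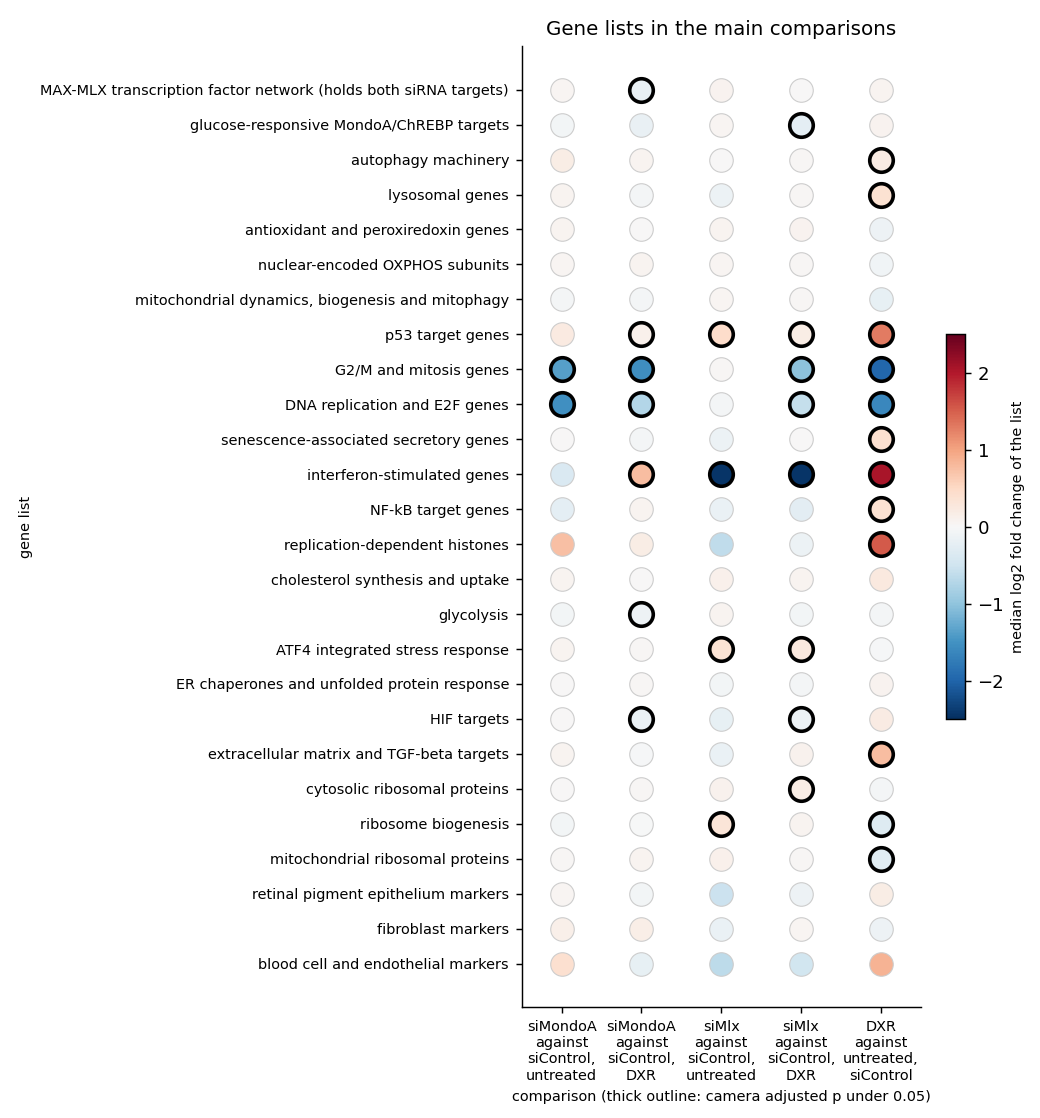
Median log2 fold change of the 26 tested lists (vertical axis) in the 5 main comparisons (horizontal axis), as colour from -2.5 (blue) to 2.5 (red). Thick outlines mark lists with a camera adjusted p under 0.05 at the preset correlation. Interferon-stimulated genes are at -2.46 and -2.45 with siMlx, 0.77 with siMondoA under DXR, and 2.07 with DXR.

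In DXR-treated cells siMondoA again lowered TXNIP, from 63.0 ± 9.2 to 4.28 ± 0.51 CPM (log2 -3.88, SE 0.24, edgeR adjusted p = 4.18e-10), and PRDX3, from 194 ± 2.9 to 72.0 ± 2.8 CPM (-1.43, SE 0.05, adjusted p = 2.27e-13). Among interferon-stimulated genes, IFIT2 went from 271 to 1210 CPM (2.15, SE 0.19, adjusted p = 9.04e-08), OASL from 27.2 to 120 (2.14, SE 0.30) and RSAD2 from 8.01 to 31.0 (1.95, SE 0.34). RRM2, a ribonucleotide reductase subunit, went from 84.2 to 18.1 CPM (-2.21, SE 0.21, adjusted p = 2.26e-07) and CCNA2 was lower by -2.17. CDKN1A was higher by 0.44 (SE 0.08, adjusted p = 0.000215), IL6 by 0.72 (SE 0.18, adjusted p = 0.00475) and LMNB1 lower by -1.54 (SE 0.22, adjusted p = 3e-05).

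The other genes with large rises were GBP4 (2.28 to 13.8 CPM, 2.59), the death ligand gene TNFSF10 (2.44), BATF2 (7.04 to 35.4 CPM, 2.33, SE 0.18, adjusted p = 1.6e-08), ISG20 (1.75), the pluripotency-related factor gene KLF4 (1.65) and SLC15A3 (1.56). XAF1 stood at 2.0 (adjusted p = 0.00174), and at an adjusted p of 0.113 with DESeq2. Large falls were seen in PABIR2 (-2.50, SE 0.15, adjusted p = 2.03e-10), BTBD10 (57.8 to 11.3 CPM, -2.35, SE 0.07), NCAPH (-2.15), EXO1 (-2.14), ASF1B (-2.10) and TROAP (-2.15, or -2.78 without DXR-treated siMondoA replicate 2). MKI67 was lower by -1.89 (SE 0.37, adjusted p = 0.000804). RUBCN was higher by 0.36 (adjusted p = 0.00629), a call that ended without DXR-treated siMondoA replicate 3 (0.0518, log2 0.20). TFEB did not pass (-0.03, adjusted p = 0.878). ARRDC4 stood at -1.74 (adjusted p = 0.0267). That call ended without DXR-treated siControl replicate 1 (0.0986) or 2 (0.0589) or siMondoA replicate 2 (0.122) or 3 (0.0744), and the value was -2.33 without siMondoA replicate 1. CDKN2A stood at 0.39 (adjusted p = 0.017), a call that ended without siControl replicate 2 (0.068) or 3 (0.0778) or siMondoA replicate 1 (0.0614) or 3 (0.0679).

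With siMondoA under DXR, 7 lists passed camera, or 6 with MLX and MLXIP left out. Of 42 interferon-stimulated genes 23 rose and none fell (32 over the list alone), with a median of 0.77 (camera adjusted p = 1.15e-08, and adjusted p = 0.672 with an estimated correlation). All 43 G2/M genes fell (median -1.56, adjusted p = 4.67e-40, and adjusted p = 0.164 with an estimated correlation), FOXM1 at -1.65 and BIRC5, survivin, at -1.91. Of 49 replication genes 38 fell (42 over the list alone; median -0.74, adjusted p = 1.44e-17, and adjusted p = 0.422 with an estimated correlation), TK1 at -1.63. Of 10 genes of the MAX-MLX network, 1 rose and 4 fell (1 and 5 over the list alone; median -0.19, adjusted p = 7.68e-05, and adjusted p = 0.149 with an estimated correlation), a call that rests on the siRNA's own target: without MLXIP and MLX it ended (0.151). MXD1 (-0.41) was among those that fell. Of 25 HIF targets 13 fell and 2 rose (median -0.17, adjusted p = 0.00376, and adjusted p = 0.164 with an estimated correlation), with TXNIP, BNIP3 (-0.53) and BNIP3L (-0.48) among them. Of 40 p53 targets 16 rose and 5 fell (17 and 6 over the list alone; median 0.12, adjusted p = 0.0395, and adjusted p = 0.672 with an estimated correlation), a call that ended without DXR-treated siControl replicate 1 (0.222) or siMondoA replicate 2 (0.0928). Glycolysis genes passed at an adjusted p of 0.0424 (11 of 24 lower and 1 higher, median -0.13, and adjusted p = 0.672 with an estimated correlation). That call ended with upper-quartile scaling (0.0547), with the stricter filter (0.0596) and without DXR-treated siControl replicate 3 (0.0654) or siMondoA replicate 1 (0.0515) or 3 (0.0733). Autophagy (median 0.06, adjusted p = 0.344) and lysosomal genes (median -0.04, adjusted p = 0.441) did not pass, and oxidative phosphorylation subunits stood at a median of 0.06 (adjusted p = 0.062, with 0.0183 without siControl replicate 2 and 0.0402 without siMondoA replicate 3). Glucose-responsive targets stood at a median of -0.18 (adjusted p = 0.062), and at 0.0354 with the replicate block, 0.0381 without siControl replicate 2 and 0.0485 without siMondoA replicate 1.

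In all, 3390 genes passed with siMondoA under DXR, 1490 higher and 1900 lower, of which 113 were higher and 294 lower by at least 2-fold. With replicate number as a block, which the correlations between numbered libraries call for here, 3830 passed. Of genes holding a word associated with lower siMondoA fold changes 25.3% were called lower, against 11.2% of those holding none. RNA45S5 was at 10.5 to 29.1 CPM with siMondoA and 10.7 to 14.1 with siControl.

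In DXR-treated cells with siMlx the interferon-stimulated gene IFIT2 went from 271 to 22.6 CPM (log2 -3.59, SE 0.22, edgeR adjusted p = 2.18e-10), OASL from 27.2 to 1.64 (-4.11, SE 0.46, adjusted p = 1.25e-06) and OAS2 from 54.8 to 3.58 (-3.97, SE 0.46, adjusted p = 1.6e-06). TXNIP fell to 9.44 ± 3.5 CPM (-2.73, SE 0.22, adjusted p = 1.2e-08), and RUBCN from 50.8 ± 2.5 to 23.2 ± 1.4 CPM (-1.13, SE 0.10, adjusted p = 2.94e-08). CDKN1A was higher by 0.49 (SE 0.08, adjusted p = 5.01e-05) and CDKN2A by 0.45 (SE 0.11, adjusted p = 0.00515). TFEB (-0.01, adjusted p = 0.972), IL6 (0.10, adjusted p = 0.739) and ARRDC4 (0.17) did not pass.

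RSAD2 (-3.62), RTP4 (-3.61), MX2 (-3.59), BATF2 (-3.21), USP18 (-3.14), ISG20 (-3.13) and OAS1 (-3.07) were also among the 10 largest falls with siMlx under DXR. Without DXR-treated siMlx replicate 1 OASL stood at -5.25, OAS2 at -4.72, RTP4 at -4.63, MX2 at -4.31, USP18 at -3.97 and OAS1 at -3.81. The largest rises were in CDC42SE2 (11.4 to 36.3 CPM, 1.67, SE 0.09, adjusted p = 3.63e-11), NAT8L (1.42), MEX3D (1.38), OTUD3 (1.32), INPP5A, an inositol phosphatase (35.6 to 85.9 CPM, 1.27, SE 0.09), RPIA (1.20), CLDN12 (1.19), DUSP8 (1.15) and KBTBD11 (1.13). PABPN1 stood at 1.11 (adjusted p = 0.0211), uncertain for a gene that a readthrough transcript overlaps. That call ended on RPKM with a pseudocount of 1 (0.0527, or 0.0512 with the filter) and without DXR-treated siControl replicate 3 (0.0747) or siMlx replicate 1 (0.135, log2 0.77). PRDX3 stood at -0.13 (adjusted p = 0.0526, and between 0.0211 and 0.0487 in 6 alternatives), and LMNB1 at -0.50 (adjusted p = 0.0627, but 0.0427 with the replicate block, 0.0119 with the compared groups alone and 6.85e-06 with no low-count filter). MKI67 stood at -1.0 (adjusted p = 0.0351). That call ended with DESeq2 (0.0533), on RPKM (0.0537 to 0.0669) and without DXR-treated siControl replicate 2 (0.0695) or 3 (0.112) or siMlx replicate 1 (0.138) or 2 (0.0817).

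With siMlx under DXR, 8 lists passed camera. None of 42 interferon-stimulated genes rose and 41 fell (41 over the list alone), with a median of -2.45, or -2.47 at the bound (camera adjusted p = 2.32e-28, and adjusted p = 0.308 with an estimated correlation), STAT2 (-1.61) and IFI35 (-2.46) among them. Glucose-responsive MondoA/ChREBP targets fell (6 of 13 lower and none higher, 7 over the list alone, median -0.24, adjusted p = 0.00915, and 0.147 with an estimated correlation). TXNIP, ARRDC3 (-1.44), ELOVL6 (-0.56) and HK2 (-0.49) were lower and hold 1, 2, 3 and 0 siMlx words, so an effect of the words is open. Of 43 G2/M genes 40 fell (median -1.03, adjusted p = 1.44e-15, and adjusted p = 0.671 with an estimated correlation), KIF4A at -2.09, and of 49 replication genes 35 fell (36 over the list alone; median -0.59, adjusted p = 3.41e-08, and adjusted p = 0.749 with an estimated correlation). Of 25 HIF targets 9 fell and 1 rose (10 and 1 over the list alone; median -0.14, adjusted p = 0.00236, and adjusted p = 0.147 with an estimated correlation), with BNIP3L at -1.09 and LDHA, lactate dehydrogenase, at -0.52. Of 40 p53 targets 19 rose and 5 fell (21 and 7 over the list alone; median 0.18, adjusted p = 0.00327, and adjusted p = 0.671 with an estimated correlation), TP53I3 at 0.73. Of 74 cytosolic ribosomal proteins 33 rose and none fell (52 over the list alone; median 0.18, adjusted p = 3.88e-07, and adjusted p = 0.806 with an estimated correlation). ATF4 targets passed at an adjusted p of 0.0241 (11 of 33 higher and 3 lower, 16 and 4 over the list alone, median 0.26, and adjusted p = 0.785 with an estimated correlation), and stood at 0.0535 without DXR-treated siMlx replicate 1.

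In all, 4129 genes passed with siMlx under DXR, 1908 higher and 2221 lower (2506 and 1953 with upper-quartile scaling), of which 76 were higher and 434 lower by at least 2-fold, and 4557 passed with replicate number as a block. Of genes holding a word associated with lower siMlx fold changes 27.3% were called lower, against 12.6% of those holding none. RNA45S5 was at 18.2 to 34.2 CPM with siMlx and 10.7 to 14.1 with siControl, and RN7SL1 and RN7SL2 together at 2.29 to 11.9 and 2.63 to 3.55.

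Under DXR, 5331 genes differed between siMondoA and siMlx, 2591 higher with siMondoA and 2740 lower (2811 and 2367 on RPKM with a pseudocount of 1), and 5773 with replicate number as a block. OASL (log2 6.25, or 7.41 without DXR-treated siMlx replicate 1), IFIT2 (5.74, SE 0.24, edgeR adjusted p = 4.61e-13), GBP4 (5.65), TNFSF10 (5.6, or 7.43 without that library) and RSAD2 (5.57) were higher with siMondoA, and MLXIP (-4.88), TNFRSF10D (422 CPM with siMlx and 75.2 with siMondoA, -2.49, SE 0.21), BTBD10 (-2.49) and GNPDA1 (-2.21) were lower. All 42 interferon-stimulated genes were higher with siMondoA (median 3.15, camera adjusted p = 2.39e-36, and adjusted p = 0.5 with an estimated correlation). Of 74 cytosolic ribosomal proteins 29 were lower (33 over the list alone; median -0.16, adjusted p = 0.00422, and adjusted p = 0.941 with an estimated correlation). G2/M genes passed at 0.00799 (12 of 43 lower, median -0.44, and adjusted p = 0.941 with an estimated correlation), and stood at 0.133 without DXR-treated siMondoA replicate 1. The siMondoA and siMlx effects under DXR had a Pearson correlation of 0.146 across genes (Spearman 0.206), and 0.488 in the simulations with no effect. The covariance was 0.028 against 0.021 there.

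DXR was also compared with untreated cells within each siRNA. With siMondoA, 7407 genes passed (3583 higher and 3824 lower), and with siMlx 8498 (4229 higher and 4269 lower). With siMondoA, TNFSF10 had 305 counts with DXR and 0 without, at least 106-fold higher over a floor of 3 counts for the group, and the sulfatase gene SULF2 had a ratio of 169 (95% counting interval 46.4 to 1400). RSAD2 (7.76, or 9.78 without untreated siMondoA replicate 2), GBP4 (7.52) and OASL (6.50, or 7.54 without that library) rose too, and FOXM1 (-3.37, SE 0.15), IL6R (75.2 to 9.08 CPM, -3.04, SE 0.19), KIF20A (-3.03), LMNB1 (-3.01) and TROAP (-3.02, or -3.66 without DXR-treated siMondoA replicate 2) fell. With siMlx, SULF2 had a ratio of 225 (95% counting interval 62.1 to 1870), OAS1 (5.98) and IFIT1 (5.38) rose, at 5.24 and 4.79 without DXR-treated siMlx replicate 1, as did CLCA2 (5.28) and COL4A3 (4.99), while SOX11 (-4.46), E2F2 (-4.19), FOXM1 (-3.99), NEURL1B (-3.93) and LMNB1 (-3.72) fell. CDKN1A rose by 2.65 with siMondoA and 2.55 with siMlx (SE 0.08 each, edgeR adjusted p = 1.45e-14 and 1.77e-14), TXNIP by 1.83 and 2.11, RUBCN by 0.84 and 0.70, TFEB by 0.72 and 0.85, CDKN2A by 0.43 and 0.51, and IL6 by 1.17 and 1.18. PRDX3 rose with siMondoA (0.20, adjusted p = 0.00332, but 0.102 to 0.104 on RPKM) and fell with siMlx (-0.61, SE 0.05, adjusted p = 3.82e-09).

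The lists followed the siControl response in most cases. With siMondoA 12 lists passed camera and with siMlx 11. For p53 targets 38 of 40 rose with siMondoA (median 1.26, camera adjusted p = 1.13e-56, and adjusted p = 0.00019 with an estimated correlation) and 37 with siMlx (median 1.10, adjusted p = 1.25e-30, and adjusted p = 0.00363 with an estimated correlation). All 42 interferon-stimulated genes rose with siMondoA (median 3.61, adjusted p = 9.18e-30, and adjusted p = 0.122 with an estimated correlation) and 38 with siMlx (40 over the list alone; median 2.19, or 2.22 at the bound, adjusted p = 5.89e-09, and adjusted p = 0.443 with an estimated correlation). All 43 G2/M genes fell with siMondoA (median -2.26, adjusted p = 5.36e-35, and adjusted p = 0.122 with an estimated correlation) and with siMlx (median -3.05, adjusted p = 2.26e-42, and adjusted p = 0.0664 with an estimated correlation). Replication genes had a median of -0.76 with siMondoA, 39 lower and 3 higher (adjusted p = 6.14e-08, and adjusted p = 0.493 with an estimated correlation), and of -2.03 with siMlx, all 49 lower (adjusted p = 1.13e-35, and adjusted p = 0.0664 with an estimated correlation). Lysosomal genes rose with siMondoA (27 of 47, median 0.28, adjusted p = 0.000612, and adjusted p = 0.122 with an estimated correlation) and with siMlx (39, median 0.50, adjusted p = 5.31e-10, and adjusted p = 0.00924 with an estimated correlation). Autophagy genes did not pass with siMondoA (21 of 43 higher and 10 lower, median 0.17, adjusted p = 0.273) but did with siMlx (24 of 43 higher and 8 lower, median 0.27, adjusted p = 0.00271, and adjusted p = 0.0664 with an estimated correlation). Secretory genes rose with siMondoA (19 of 34, median 0.41, adjusted p = 0.000629, and adjusted p = 0.17 with an estimated correlation) and siMlx (23, median 0.62, adjusted p = 6.12e-07, and adjusted p = 0.0537 with an estimated correlation).

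Histones rose with siMondoA (9 of 13, median 1.00, camera adjusted p = 2.49e-06, and adjusted p = 0.0545 with an estimated correlation) and siMlx (10, median 1.88, adjusted p = 8.38e-07, and adjusted p = 0.0314 with an estimated correlation), and matrix genes rose with siMondoA (27 of 36, median 0.83, adjusted p = 8.01e-09, and adjusted p = 0.224 with an estimated correlation) and siMlx (29, median 1.10, adjusted p = 6.44e-10, and adjusted p = 0.166 with an estimated correlation). NF-kB targets rose with siMondoA (13 of 23, median 0.57, adjusted p = 0.00046, and adjusted p = 0.122 with an estimated correlation). Ribosome biogenesis genes fell with siMondoA (18 of 35, median -0.17, adjusted p = 0.00607, and adjusted p = 0.312 with an estimated correlation) and siMlx (32, median -0.53, adjusted p = 1.25e-10, and adjusted p = 0.0314 with an estimated correlation). Mitochondrial ribosomal proteins fell with siMondoA (49 of 67, median -0.26, adjusted p = 1.28e-05, and adjusted p = 0.312 with an estimated correlation) and siMlx (56, median -0.36, adjusted p = 2.6e-07, and adjusted p = 0.2 with an estimated correlation). Genes of mitochondrial dynamics passed with siMondoA at 0.0425 (18 of 31 lower, median -0.19, and adjusted p = 0.122 with an estimated correlation), but not with the replicate block (0.0635) or without untreated siMondoA replicate 1 (0.0685) or DXR-treated siMondoA replicate 2 (0.0513).

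Whether each siRNA changed the response to DXR was tested as an interaction. With siMondoA, 1384 genes passed, 798 with a more positive and 586 with a more negative DXR response than with siControl (655 and 788 with upper-quartile scaling), and 918 without untreated siMondoA replicate 1. With siMlx, 1675 passed, 880 more positive and 795 more negative (652 and 1051 on RPKM with a pseudocount of 1). CDKN1A responded less with siMondoA (log2 difference -0.70, SE 0.11, edgeR adjusted p = 0.000379) and with siMlx (-0.79, SE 0.11, adjusted p = 6.64e-05), and was already higher in untreated cells with both. PRDX3 had a difference of 0.50 with siMondoA (SE 0.07, adjusted p = 0.000263) and of -0.31 with siMlx (SE 0.07, adjusted p = 0.00724), and LMNB1 fell further with siMlx (-1.08, SE 0.24, adjusted p = 0.00627). The TXNIP response did not differ past the test (siMondoA -0.42, adjusted p = 0.641, but 0.0097 on RPKM with a pseudocount of 1; siMlx -0.14, adjusted p = 0.869), nor did LMNB1 (-0.37, adjusted p = 0.446) or MKI67 (-0.52, adjusted p = 0.562, but 0.000137 with no low-count filter) with siMondoA. With siMondoA, IFIT2 (2.49, SE 0.29, adjusted p = 2.74e-05) responded more. With siMlx, NEK7, a mitotic kinase gene, was 173 CPM with siControl and 20.4 with siMlx in untreated cells, and 281 and 144 with DXR (2.12, SE 0.17, adjusted p = 1.81e-07). Among lists, 3 passed camera with siMondoA and 9 with siMlx, and 0 with an estimated correlation. With 1 library left out they were 3 to 9 and 8 to 10.

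The siRNA and DXR effects were compared across genes with contrasts that share no library. The siMondoA effect in untreated cells and the DXR effect with siMlx had a Pearson correlation of 0.303 (0.246 to 0.36 with 1 library left out), with 1374 genes higher in both (985 if independent) and 1667 lower in both (996 if independent). The siMlx effect in untreated cells and the DXR effect with siMondoA had a correlation of -0.128 (-0.169 to -0.049 with 1 library left out, and -0.048 to 0.05 in simulated unchanged groups), with 814 genes higher in both (893 if independent) and 937 lower in both (879 if independent). Genes are not independent replicates.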

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

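The results below were singled out because the response to DXR differed between an siRNA and siControl by the interaction term of the edgeR fit, or because a pattern across genes invited a technical explanation. The tests of single libraries, of the 3′ UTR words held by interferon-stimulated and by G2/M genes, of CDKN1A and of other splits of the libraries were chosen only after the results were seen. The searches for 3′ UTR words with siMondoA and in PRDX3, and the test of interferon receptors and kinases, were written down beforehand.

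Genes lower with siMondoA and not with siMlx, PRDX3 among them, may in part be off-target effects of the siRNA, which can act like a microRNA through short matches in 3′ UTRs. The 7-base word most associated with lower siMondoA fold changes, TCCAGTA, had a z of -14.96, where the lowest of 200 shuffles was -4.96. Found on one part of the genes, the word ranked 1 in the other part (z -11.21), while the top word for DXR in siControl cells ranked 5283 there. The siMlx effect had such a word too (CTGGTCA, z -15.26, lowest shuffle -5.26), so neither siRNA's effect is free of this signal. For PRDX3 the annotated 3′ UTR of 777 bases held 0 of the 3 top siMondoA words, which argues against those words in that UTR, but sites in the coding sequence, weaker words and loss of MondoA itself stay open, and the siRNA sequences were not used here.

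Interferon-stimulated genes were lower with siMlx in both conditions (adjusted p = 0.815 and 0.308 for the list with an estimated correlation). With each library left out in turn the highest median of the list was -2.12, which argues against 1 aberrant library. Members whose 3′ UTR held none of the 3 top siMlx words (28 of 42) had medians of -2.84 in untreated and -2.59 with DXR, lower than the 14 members holding a word (-1.84 and -2.01), which argues against direct repression of these genes through those words. Loss of a shared upstream gene could still account for it: among receptor and kinase genes IFNAR2 was lowest (-0.81 untreated and -0.85 with DXR), with a fold change minus 2 SE of -1.04, so a 2-fold loss cannot be excluded, while IFNAR1 (-0.10 and -0.09), JAK1 (0.01 and 0.07) and TYK2 (-0.40 and -0.26) moved less. An action of MLX on the pathway was not tested apart from this, and it stays open with an off-target effect on an upstream gene.

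G2/M and mitosis genes were lower with siMondoA in untreated cells (adjusted p = 0.876 for the list with an estimated correlation). With each library left out in turn the highest median was -1.22, which argues against 1 aberrant library. CDKN1A rose at least as much with siMlx, where the list's lower quartile was -0.15 (siMondoA median -1.38), but other siMlx effects could offset it. A CDKN1A role, loss of MondoA and an off-target slowing of the cell cycle stay open. CCNA2 and NCAPH hold siMondoA words, CDC20 and ANLN none.

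In each of the 9 comparisons of 3 libraries with 3, only the real of 10 splits gave as many genes in edgeR. The others gave 0, and so few splits cannot go under a share of 0.1. For the interactions, 12 of 100 splits with siMondoA (real 1384, highest other 4621) and 8 of 100 with siMlx (real 1675, highest other 4405) gave as many, so chance is not excluded by this count. The others that gave as many are unbalanced swaps that put the siRNA effect into the contrast. Balanced splits (43 and 40, a choice made after the result) gave 0 except the real one. Splits that mix groups turn group differences into spread, so these 0s do not decide.

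The interaction of siMondoA with DXR passed for 1384 genes (918 without untreated siMondoA replicate 1). Positive differences in log2 units, all past the edgeR threshold, were 0.50 for PRDX3, 2.52 for OASL, 2.49 for IFIT2, 2.49 for BATF2, 2.30 for HERC5 and 2.11 for ARSI. Negative ones were -0.63 for MLXIP, -0.70 for CDKN1A, -1.97 for TTC29, -1.80 for FANK1, -1.76 for RBM47, -1.59 for LINC01123 and -1.58 for CSMD3. The MLXIP call (adjusted p = 0.0469) ended in 13 alternatives, with adjusted p up to 0.541, among them every fit without 1 library except those without untreated siControl replicate 2, untreated siMondoA replicate 1 and DXR-treated siMondoA replicate 3. The OASL call ended with DESeq2 (0.0808) and without untreated siControl replicate 1 (0.187) or 3 (0.0516), untreated siMondoA replicate 1 (0.0956) or 3 (0.0683), DXR-treated siControl replicate 2 (0.0534) or 3 (0.0559) or DXR-treated siMondoA replicate 3 (0.0552), and its value was 3.56 without untreated siMondoA replicate 2. The TTC29 call ended without untreated siControl replicate 1 (0.0507) or DXR-treated siControl replicate 2 (0.0591) or 3 (0.0785). Among lists, replication genes had a positive median difference of 0.77 (21 of 49 higher and 1 lower, 34 and 1 over the list alone, camera adjusted p = 4.48e-21, and adjusted p = 0.476 with an estimated correlation), with BRCA2 at 1.70. Interferon-stimulated genes had one of 1.24 (17 of 42 higher, 26 over the list alone, adjusted p = 9.2e-15, and adjusted p = 0.567 with an estimated correlation). Lysosomal genes had one of -0.08 (5 of 47 lower, 6 over the list alone, adjusted p = 0.00441, and adjusted p = 0.476 with an estimated correlation).

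The interaction of siMlx with DXR passed for 1675 genes. Positive differences were 2.96 for IFIT1, 2.12 for NEK7, 2.09 for BEX4, 1.87 for LMOD1 and 1.85 for SYT12. Negative ones were -0.36 for MLX, -0.31 for PRDX3, -0.79 for CDKN1A, -1.08 for LMNB1, -1.96 for NEURL1B, -1.96 for BATF3, -1.94 for LRATD1, -1.56 for CDC25C and -1.52 for ESM1. The MLX call (edgeR adjusted p = 0.036) ended in 12 alternatives, with adjusted p up to 0.201, the IFIT1 call on RPKM with a pseudocount of 1 (0.249) and without untreated siMlx replicate 2 (0.0533), with a value of 2.16 without untreated siControl replicate 1, and the LRATD1 call on the same scale (0.745) and without untreated siControl replicate 1 (0.0655). Among lists, G2/M genes had a median difference of -1.02 (31 of 43 lower, 40 over the list alone, camera adjusted p = 7.03e-23, and adjusted p = 0.42 with an estimated correlation), replication genes -0.60 (18 of 49 lower, 26 over the list alone, adjusted p = 8.18e-12, and adjusted p = 0.481 with an estimated correlation) and p53 targets -0.26 (16 of 40 lower and 4 higher, adjusted p = 6.93e-05, and adjusted p = 0.42 with an estimated correlation). Ribosome biogenesis genes stood at -0.28 (17 of 35 lower, adjusted p = 6.82e-09, and adjusted p = 0.158 with an estimated correlation), lysosomal genes at 0.13 (8 of 47 higher, adjusted p = 0.000746, and adjusted p = 0.277 with an estimated correlation) and secretory genes at 0.22 (7 of 34 higher and 2 lower, adjusted p = 0.00965, and adjusted p = 0.437 with an estimated correlation). Matrix genes stood at 0.23 (5 of 36 higher, adjusted p = 0.00429, 0.0859 without untreated siMlx replicate 3, and adjusted p = 0.642 with an estimated correlation). Cytosolic ribosomal proteins, at 0.09 (adjusted p = 0.0306, and adjusted p = 0.827 with an estimated correlation), lost the call when any of 6 libraries was left out (0.0591 to 0.444), and mitochondrial ribosomal proteins, at -0.08 (adjusted p = 0.0186, and adjusted p = 0.642 with an estimated correlation), lost it with any of 4 (0.0511 to 0.115).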

How the results depend on the processing

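Over all alternatives, the calls of 1331 pairs of a gene and a comparison were the same in 22006 cases, ended in 469 and were gained in 140, and no gene changed direction where it was called. Leaving out 1 library accounts for 347 of the ended calls. Counts of genes stayed within 1.5 times under every alternative except for the interaction of siMondoA with DXR without untreated siMondoA replicate 1 (918), and the cause was not tested. With 1 library left out in turn, 5567 to 5966 genes passed for siMondoA in untreated cells, 5628 to 6223 for siMlx, 6909 to 7241 for DXR in siControl cells, 2697 to 2907 for siMondoA and 3355 to 3723 for siMlx under DXR. For DXR within siMondoA and siMlx they were 6677 to 6868 and 7900 to 8173, for siMondoA against siMlx 7356 to 7693 untreated and 4635 to 4882 with DXR, and for the interactions 918 to 1384 with siMondoA and 1220 to 1794 with siMlx.

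The number of lists passing depends on the list test. In the order of the 5 main comparisons (siMondoA untreated, siMlx untreated, DXR in siControl, siMondoA with DXR, siMlx with DXR), camera with an estimated correlation passed 0, 0, 3, 0 and 0 lists and fry 14, 15, 22, 13 and 15. For DXR in siMondoA and siMlx and siMondoA against siMlx untreated and with DXR, the estimated correlation gave 1, 4, 0 and 0 and fry 19, 20, 19 and 7, and for both interactions the estimated correlation gave 0. Camera estimates the correlation between list members from the residuals, and fry does not compare a list with other genes. With MLX and MLXIP left out of the lists, which was chosen after seeing the data, 6 lists passed for siMondoA with DXR, and the other counts stayed. With 1 library left out, 2 to 3, 4 to 6, 11 to 13, 6 to 9 and 7 to 9 lists passed in the 5 main comparisons, 11 to 12 and 11 to 12 for DXR in siMondoA and siMlx, 6 to 7 and 3 to 4 for siMondoA against siMlx, and 3 to 9 and 8 to 10 for the interactions. The siMondoA interaction reached 9 lists without DXR-treated siControl replicate 1, 8 without DXR-treated siMondoA replicate 2 and 5 without untreated siControl replicate 2 or untreated siMondoA replicate 2 or 3.

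Similarities with 1 library left out ran from 0.121 to 0.191 (siMondoA and siMlx, untreated), 0.11 to 0.213 (with DXR), 0.189 to 0.228 (siMondoA untreated and siMlx with DXR), -0.03 to 0.009 (siMlx untreated and siMondoA with DXR), 0.246 to 0.36 (siMondoA untreated and DXR in siMlx) and -0.169 to -0.049 (siMlx untreated and DXR in siMondoA). The similarity of -0.003 changed sign without untreated siControl replicate 1 (0.009) and DXR-treated siControl replicate 3 (0.001), and the cause was not tested. With the filter of 1 CPM in 3 libraries, 2 similarities moved, to 0.256 and 0.341, where fewer genes of low count are compared.

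On RPKM with a pseudocount of 1 the median gene stood at -0.065 for DXR in siControl, -0.089 in siMondoA and -0.085 in siMlx, and calls shifted toward lower: 2935 higher and 4888 lower for DXR in siControl, 2691 and 5245 in siMondoA, and 3167 and 5522 in siMlx. The other RPKM settings shifted the same way. The siMlx interaction without DXR-treated siMlx replicate 1 gave 943 higher and 502 lower. Libraries with the same replicate number had residual correlations of -0.08 to 0.28 (mean 0.09, other numbers -0.04), and 15 of 18 libraries were on average closest to their own number. In the 3 comparisons between siRNAs under DXR all 3 pairs correlated, and the replicate block gained LMNB1 (siMlx, 0.0427), MKI67 (siMondoA against siMlx, 0.0307) and LPIN1 there. Over all comparisons it gained 20 calls of named genes and ended 0. ARRDC4, MLXIPL and GDF15 are limited by depth.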

Other observations

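The summed histone levels were chosen only after the data were seen, and the gene and list tests were planned. Among antioxidant genes (10 of 32 higher and 8 lower, median 0.06, camera adjusted p = 0.829, siMlx in untreated cells) the NRF2 targets GCLM (log2 -0.93, SE 0.10, edgeR adjusted p = 2.14e-07), NQO1 (-0.70, SE 0.07) and GSR (-0.70, SE 0.07) fell, and PGD rose (0.57, SE 0.06). NQO1 holds 2 of the words associated with lower siMlx fold changes, and GCLM and GSR hold 0. Retinal pigment epithelium markers stood at a median of -0.54 with siMlx (1 of 13 higher and 6 lower, adjusted p = 0.259), with the transcription factor gene MITF at -0.75, and at 0.18 with DXR in siControl cells (adjusted p = 0.157), where KRT8 (1.00) and TYRP1 (3.21) rose.

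Summed levels of the listed replication-dependent histone genes, which poly(A) selection captures poorly, averaged 79.2 CPM in untreated siControl libraries, 59.5 with siMlx and 137 with siMondoA, and 223, 206 and 276 with DXR in the same order.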
